A study of Rattus norvegicus with 12 samples.

How the data were processed

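Hippocampal RNA was sequenced from 12 male Sprague-Dawley rats of 8 weeks whose adrenal glands, the main source of circulating glucocorticoid, had been removed. The 6 rats given corticosterone at 300 µg/kg and the 6 given vehicle each enter the deposited table as 1 pooled value per assembled gene. The hippocampi were taken 1 h after treatment. The titles of the samples gave the groups, and the conditions named Cort and Control in the table were matched to the corticosterone and vehicle titles. The labels conflict on the compound: the source names of the 6 treated samples say cortisone, while their titles and the extraction protocol say corticosterone, which is followed here.

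The reads were processed by the authors. Bowtie2 0.6, TopHat 0.9, Cufflinks 2.2.1.0 and Cuffdiff 2.2.1.3 are listed in the submitters' processing notes, with no order or settings. The scaling method, the dispersion model, the strand setting and the multiple-read correction are not given in the sources used here. The same notes name the rat build rn5. The table, however, holds 10 entries on a Y chromosome and 106 on scaffolds whose names begin with KL or AABR07, which are names of the rn6 (Rnor_6.0) assembly. Coordinates are therefore printed exactly as the table gives them and are best read as rn6. Whether starts count from 0 or 1 is not given in the sources used here. The reference table at hand is of another rat assembly (GRCr8), so it was not joined by position.

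Per the file headers, the gene table holds FPKM values (fragment counts scaled for transcript length and sequencing depth), 1 per group and assembled gene, as the authors' Cuffdiff run wrote them. The deposited log2 fold change is Control over Cort, checked on 58263 entries with both values above 0, of which 58263 matched log2 of the value ratio within 0.001. Its sign was turned here, so that a positive value means higher with corticosterone, and folds are 2 to the power of its size. The authors' p-values and q-values were used as deposited. The q-values differed from a Benjamini-Hochberg adjustment over the 42839 tested entries by at most 5.11e-07. The deposited test statistic, a score, was not used for any value below. The second file, also deposited by the authors, lists assembled transcripts with a position and a score that takes a lower or a higher code, whose meaning is not given in the sources used here.

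The table has 58341 assembled genes at 25606 distinct loci. Cuffdiff tested 42839 of them at 17079 loci. It left 15485 untested, all with a mean value of at most 0.81 FPKM, and marked 8 as failed and 9 as holding too many fragments. An assembled gene is called different where the deposited q was 0.05 or less, which matched the authors' own mark in every entry. No new test across animals could be fitted from 1 value per group, so no SD or SE is given. The spread between animals is not known here. How far the authors' q takes it into account cannot be told without the dispersion model. Read depth per sample is unknown, and no counting interval is given for that reason. Values of 0 are given as listed at 0.

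None of the 58341 entries carries a gene symbol, and the files do not pair the assembled genes with names. The 13 pathway lists and 12 cell type marker lists fixed before the data were examined matched 0 entries and were not analysed here, nor was the mitochondrial genome. The rule for named genes was fixed at the same time: the 12 called genes with a symbol and the largest rise, the 12 with the largest fall, each with at least 1 FPKM in a group, plus set genes by symbol. After the data were seen, its first part was applied without the symbol condition and to loci, each represented by its most abundant called assembled gene. The 2 called loci listed at 0 in a group meet the rule but have no finite fold to rank, so they were left out of the 24 and are given separately. The comparisons within loci, between neighbouring loci and between chromosomes, and the loci singled out for abundance, for several called genes, for their neighbours or from the transcript list, were likewise chosen after the values were seen.

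Called loci were joined where 100 kb or less lay between them. Called and uncalled loci of 21 chromosomes were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Where several assembled genes shared a locus, the median log2 fold change of the less abundant ones was compared with that of the most abundant one. These differences were set beside 10000 random sets of loci, and the spacing of called loci beside 1000 random sets, all matched on mean FPKM in 20 bins. The within-locus script was tested on simulated data over the 42839 tested entries: with 200 loci changed and an extra log2 change of 0.5 planted in their less abundant entries it returned 0.51, and with no extra change it returned 0.005. The simulated noise was the same at every abundance, and the calls were set directly. The simulation therefore checks the calculation, and not the effect of noise at low values or of selection by the call threshold. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the q threshold, a filter at 1 FPKM, a pseudocount of 0.1 or 1, and a minimum change of 1.5 times. They also covered recentring on the median entry among those with a mean of at least 1 FPKM, and counting loci or joined regions once.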

Results

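The comparison asks which hippocampal transcripts differ 1 h after corticosterone, the main glucocorticoid of the rat, in animals whose adrenal glands had been removed. The data are 1 pooled FPKM value per group for each assembled gene, from 6 corticosterone-treated and 6 vehicle-treated adrenalectomised rats. The tested assembled genes had a median of 2.17 FPKM with corticosterone and 2.15 FPKM with vehicle. Their median log2 fold change was 0.007. All fold changes, p-values and q-values below are from the authors' deposited table, and no replicate error is given because each group is a single pooled value.

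Of the 42839 tested assembled genes, 148 were called different, and most of these were higher with corticosterone. By the q-values of the authors' deposited table, 116 assembled genes were higher, at 94 loci, and 32 were lower, at 32 loci. Among called genes with both values above 0, the largest increase in the authors' deposited table was 5.72-fold and the largest decrease 2.68-fold. A further gene in each direction is listed at 0 in a group and has no fold. The median change of the called genes with a fold was 1.74-fold for increases and 1.49-fold for decreases in the authors' deposited table, but 30 of the increases shared 8 loci. With the most abundant called gene of each locus alone, the medians in the authors' deposited table were close, 1.57-fold and 1.49-fold, and 28 of the 93 higher loci and 2 of the 31 lower loci with both values above 0 reached 2-fold. No locus held called genes of both directions. The called loci were 0.738% of the 17079 loci tested.

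**Figure D1:**
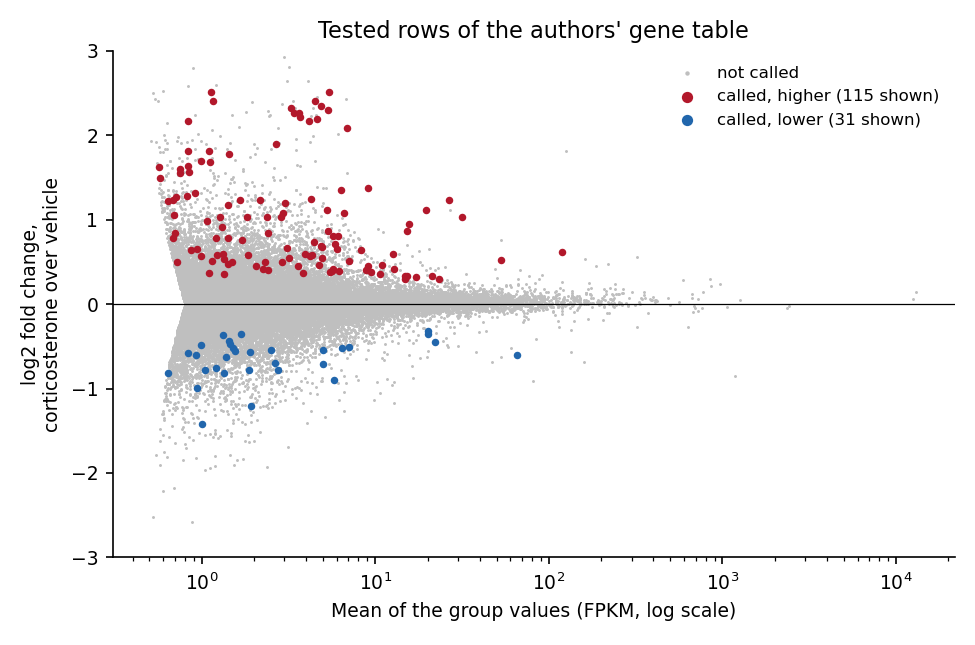
Each point is an assembled gene of the authors' table, with the mean of its group values (FPKM, log axis) against its log2 fold change, corticosterone over vehicle; grey points were not called, red points were called higher and blue points called lower. The 115 called increases and 31 called decreases with both values above 0 are drawn, the increases reach further from 0, and 8 uncalled points lie beyond the axis limit of 3.

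Among loci with both values above 0, the largest increase of a locus's leading called gene lay on an unplaced scaffold, chrUn_KL568465v1. Its entry at 92696 to 106269 rose from 1.08 FPKM with vehicle to 5.44 FPKM with corticosterone, 5.02-fold in the authors' deposited table, and the adjoining entry at 106445 to 109486 rose from 1.18 to 5.65 FPKM. Another increase, on chromosome 4 at 30544867 to 30556615, was from 1.14 to 4.23 FPKM. On chromosome 14, the locus at 19176276 to 19182352 rose from 0.65 to 2.21 FPKM. On chromosome 15, that at 58873202 to 58879138 rose from 0.37 to 1.13 FPKM. More abundant members of this group were the locus on chromosome 6 at 76266869 to 76270678, which rose from 5.07 to 13.2 FPKM, and the locus on chromosome 20 at 7974577 to 8087005, which rose from 3.56 to 9.06 FPKM. The last of these is followed at 8103202 to 8105037 by a separate locus that rose 3.51-fold in the authors' deposited table. Each of these increases had the smallest q of the authors' deposited table, 0.0165. The remaining loci of the 12 with the largest such rise and at least 1 FPKM in a group lay on chromosomes 2, 6, 9 and X. Their most abundant called genes rose between 2.41-fold and 3.21-fold in the authors' deposited table. On X, at 111884244 to 111943904, that was a sparse gene, from 0.42 to 1.01 FPKM. The most abundant gene there had 19.5 FPKM with vehicle and 26.2 with corticosterone and was not called (q = 0.103).

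Among loci with both values above 0, the largest decreases were smaller than the largest increases. The genes that fell had a median of 2.05 FPKM with vehicle and 1.26 FPKM with corticosterone. On chromosome 8, the locus at 62919797 to 62943063, assembled gene XLOC_051591, fell from 1.46 FPKM with vehicle to 0.54 FPKM with corticosterone, 2.68-fold in the authors' deposited table. That on chromosome 5 at 173624368 to 173626375, assembled gene XLOC_041537, fell from 2.68 to 1.16 FPKM, 2.31-fold in the authors' deposited table. A more abundant locus on chromosome 11 at 38035473 to 38059798 fell from 7.56 to 4.06 FPKM, and that on chromosome 7 at 77155962 to 77162549 fell from 6.21 to 3.81 FPKM. On chromosome 17, a sparse gene of the locus at 24242553 to 24295095 fell from 1.72 to 0.97 FPKM, while the most abundant gene there had 5.23 FPKM with vehicle and 4.85 with corticosterone and was not called. The other 7 of the 12 largest decreases with both values above 0 and at least 1 FPKM in a group ranged from 1.55-fold to 1.99-fold in the authors' deposited table, with q between 0.0165 and 0.0434.

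**Figure D2:**
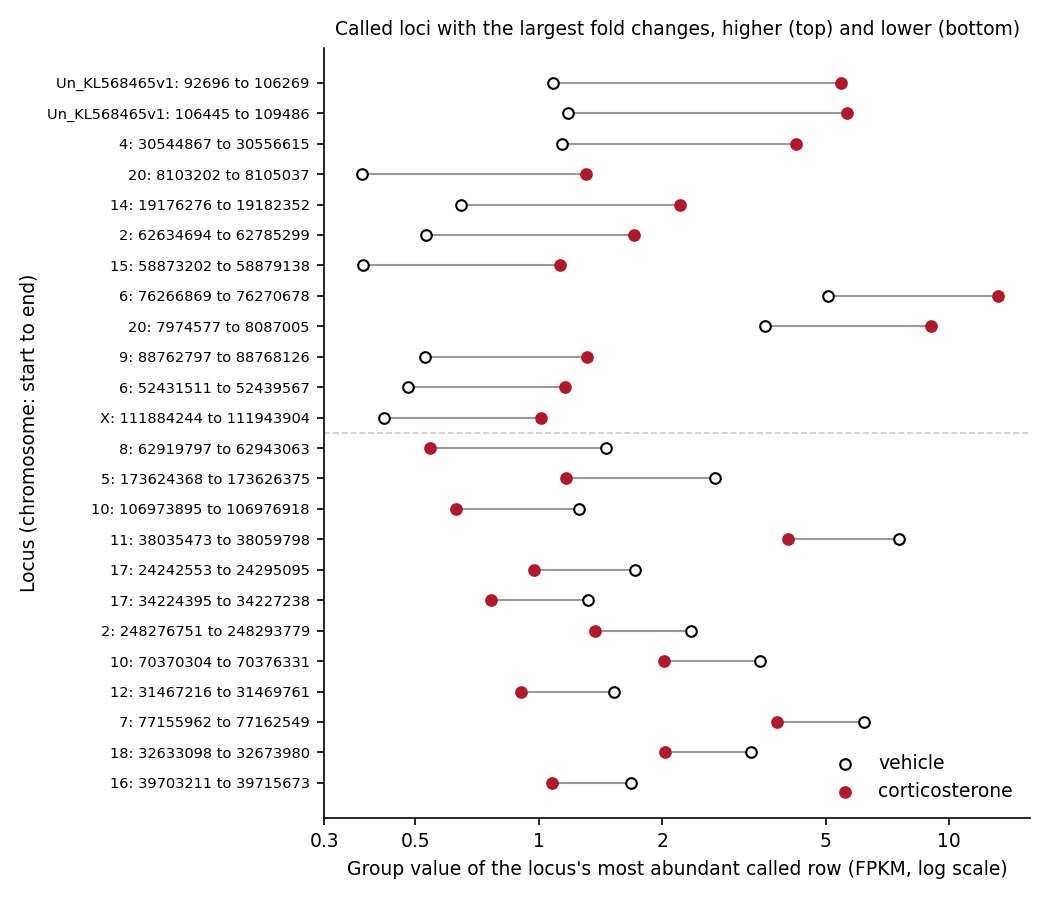
FPKM (log axis) of the most abundant called gene at each of 24 called loci with both values above 0 and at least 1 FPKM in a group, with vehicle as open circles and corticosterone as filled circles, for the 12 largest increases among such loci above the dashed line and the 12 largest decreases below it. The lines join the pooled values of a locus, and the increases span more of the axis than the decreases.

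A few abundant transcripts were among the calls. The most abundant lay on chromosome 10 at 15589356 to 15603667 and rose from 93.9 FPKM with vehicle to 143.7 FPKM with corticosterone, 1.53-fold in the authors' deposited table. In that table, the locus on chromosome 1 at 24185451 to 24302581 rose from 15.8 to 37.3 FPKM, 2.36-fold, and a short entry on chromosome 20 at 3677476 to 3677838 rose from 20.8 to 42.5 FPKM, 2.04-fold. The most abundant decrease was on chromosome 6 at 127327603 to 127334442, from 79.0 to 51.9 FPKM. Of the 691 tested genes with a mean of at least 50 FPKM, 3 were called, or 0.434%. The share in the lower abundance bins was between 0.286% and 0.503%. None of the 12 most abundant tested genes of the authors' deposited table was called, and their smallest unadjusted p was 0.0499, with a smallest q of 0.999. However, 8 of these 12 were short entries spanning less than 600 bp. A gene of the locus on chromosome 20 at 28214245 to 28262996 was called with 1.44 FPKM with corticosterone and is listed at 0 with vehicle, and a gene on chromosome 1 at 36952165 to 36952536 was called with 2.22 FPKM with vehicle and is listed at 0 with corticosterone.

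Several increases spread over many assembled genes of 1 locus. On chromosome 8, the locus at 52980103 to 53147051 held 42 tested genes, and all 42 had a higher value with corticosterone, of which 10 were called. Its most abundant gene, XLOC_052018, rose from 12.5 to 26.9 FPKM, 2.16-fold, and the other called genes there rose up to 5.70-fold in the authors' deposited table. On chromosome 20, the locus at 7974577 to 8087005 held 8 tested genes, all with higher values, of which 3 were called, and XLOC_031924 among them rose 5.72-fold, from 0.34 to 1.94 FPKM in the authors' deposited table. By the same table, chromosome 7 at 125569769 to 125612977 had 11 tested genes, all with higher values, and 3 calls between 2.05-fold and 4.48-fold. A locus on chromosome 2 at 62634694 to 62785299 had 5 calls between 2.93-fold and 3.52-fold in the authors' deposited table, while its most abundant gene, with 3.72 FPKM with vehicle and 6.88 with corticosterone, was not called (q = 0.747). In all, 8 loci held at least 2 called genes, together 30 of the 148, and all 8 were higher with corticosterone.

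Within called loci the less abundant genes tended to have larger fold changes than the most abundant one, whether or not they were called themselves. The most abundant tested gene was called higher at 29 loci with further tested genes, and at 26 of these the median fold change of the others was larger. In the authors' deposited table the most abundant genes had a median log2 fold change of 0.58, 1.49-fold, and the medians of the others had a median of 1.07, 2.10-fold. The difference was 0.48 on the log2 scale (interquartile range 0.12 to 0.73, over 29 loci). On chromosome 16, the leading gene at 18861136 to 18894926 had a log2 fold change of 0.45 in the authors' deposited table and the others, none of them called, a median of 1.86. One on chromosome 1 at 24185451 to 24302581 went the other way in the authors' deposited table, with 1.24 for its leading gene and a median of -0.29 for the other 12, none of which was called. At the 2 loci whose most abundant gene was called lower, the other gene of each, not called, had a log2 fold change of -0.32 and -0.50 in the authors' deposited table, against -0.35 and -0.50. With a pseudocount of 1, which compresses low values, the pattern was largely lost. The less abundant genes then had the larger change at 18 of the 29 loci, with a median difference of 0.054 (interquartile range -0.057 to 0.27).

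**Figure D3:**
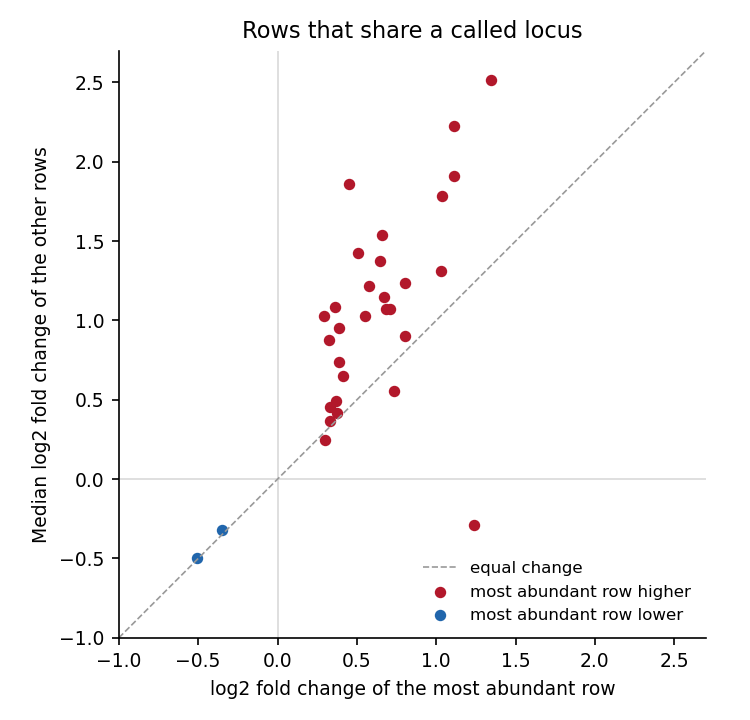
Each point is a locus with at least 2 tested genes whose most abundant gene was called, with the log2 fold change (corticosterone over vehicle) of its most abundant gene on the horizontal axis and the median log2 fold change of its other tested genes on the vertical axis. Of the 29 loci with a higher leading gene (red), 26 lie above the dashed line of equal change, and the 2 with a lower leading gene (blue) lie close to it.

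Called loci also lay side by side. When loci within 100 kb were joined, the 126 called loci formed 104 regions, of which 78 were higher, 25 lower and 1 mixed. Of these, 15 regions held 2 or more called loci, and 14 of the 15 changed in a single direction. On chromosome 12, 5 loci between 31394870 and 31469761 fell between 1.36-fold and 1.68-fold in the authors' deposited table, and all 3 uncalled genes among them had lower values, while 3 loci between 28598826 and 28679208 on the same chromosome rose between 1.28-fold and 1.41-fold. Sets of 3 neighbouring increases were also found on chromosome 6 between 43195714 and 43223868 and on chromosome 11 between 69465502 and 69604522. The mixed region was on chromosome 3, where the locus at 60051379 to 60105650 rose 1.26-fold in the authors' deposited table and 2 loci up to 60235270 fell. Chromosomes 12 and 11 had the highest shares of called loci, with 10 of 539 and 10 of 582 tested loci, but no chromosome passed Fisher's exact test over 21 chromosomes (smallest Benjamini-Hochberg adjusted p = 0.116), which treats neighbouring loci as independent.

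The authors' list of different transcripts covered much of the same ground. It names 122 assembled transcripts at 95 loci, of which 103 sit at loci with a called gene, with identical start and end. The higher score code stood at 86 transcripts of loci called higher and 0 of loci called lower, and the lower code at 17 transcripts of loci called lower and 0 of loci called higher. Both lists come from the authors' own analysis and use the same assembled loci, so this match is not independent evidence for the calls. Of the 126 called loci, 77 are in the list and 49 are not, 34 of them higher and 15 lower. The other 19 transcripts, at 18 loci, had no called gene. The list is of transcripts while the values that follow are of assembled genes, so they need not match. One of these loci, on chromosome 10 at 66322107 to 66482609, holds 2 listed transcripts, and its most abundant gene had 5.97 FPKM with vehicle and 10.2 with corticosterone in the authors' deposited table (q = 0.825). Another, on chromosome 8 at 23380535 to 23385242, had 0.56 and 1.12 FPKM and a q of 0.0546 in the authors' deposited table, just above the threshold. At the locus on chromosome 10 at 40812806 to 40846339 the gene values were nearly equal, 10.6 and 10.7 FPKM in the authors' deposited table (q = 0.999).

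The precision of these calls is bounded by the resolution of the p-values. The smallest p of the authors' deposited table was 5e-05, shared by 130 of the 148 calls, so most calls cannot be ranked by significance. Of its tested genes, 1253 had an unadjusted p of 0.05 or less, fewer than the 2142 that evenly spread p-values would give, and 71.5% had a p above 0.5. The p-values lean towards high values. The 2142 is therefore not a measure of chance results here, and the 148 calls are not an estimate of how many genes responded.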

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

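The alternatives that join called loci or leave a locus out, those for the named loci and all comparisons within loci were chosen after seeing the data. The 148 calls, 116 higher and 32 lower, changed in number by no more than 1.5 times under a q of 0.10 or less (178), adjustment over genes with a mean of at least 1 FPKM (121, all among the 148), values above 1 FPKM, loci counted once, loci within 10 or 100 kb joined, and without the chromosome 8 locus that holds 10 calls. A q of 0.01 or less left 0 calls, 0 higher and 0 lower, because the smallest q is 0.0165; 1253 genes had an unadjusted p of 0.05 or less. A change of at least 1.5 times left 93 calls, 77 higher and 16 lower. Joining loci within 1 Mb left 98 regions, 73 higher, because fewer units are counted. Within loci, the less abundant genes had the larger increase at 24 of 27 loci from uncalled genes alone, 22 of 26 with a mean of at least 1 FPKM, 26 and 18 of 29 with pseudocounts of 0.1 and 1, and 25 of 28 without the chromosome 8 locus. The pseudocount of 1 also lowered the median log2 difference to 0.054 (interquartile range -0.057 to 0.27), so this pattern depends on how low values are treated. The 103 listed transcripts at called loci were as many with 50% overlap and with identical ends. All 122 listed transcripts share both ends with an assembled locus, so the overlap settings say nothing about stability either. Adjustment over all tested genes repeats the deposited q, recentring by 0.009 leaves q as it is, and neither it nor a pseudocount can turn the direction of a named locus, so these say nothing about stability. Higher calls outnumbered lower ones in every alternative that left calls. No paired analysis was possible because each group is deposited as 1 pooled value; for the same reason leaving out animals was not run. Gene list alternatives and adjustment over genes with a symbol were not run, since no entry carries a symbol. Depth per animal is unknown, so what the sparse genes could show is not bounded here.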

Other observations

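The tests of selection by the call threshold, noise of low values, unspliced RNA, scaling, repeated counting and chance placement were chosen only after the patterns they bear on had been seen. Loci next to the called ones tended to differ in the same direction without being called. Among 87 uncalled loci within 10 kb of a called locus, 78 had a value that differed in the direction of that locus, with a median log2 difference of 0.24 in that direction. At 10 to 100 kb the figures were 158 of 229 loci and 0.063, and at 100 kb to 1 Mb they were 811 of 1489 loci and 0.015. Matched random loci more than 1 Mb from any call gave medians up to 0.036, 0.022 and 0.013 at the upper end of their central 95%. Below the threshold there were more increases too: 666 uncalled genes with an unadjusted p of 0.05 or less had higher values and 439 had lower ones. These counts include uncalled genes at and next to called loci, which tended to follow them. They are therefore not separate evidence of an excess of increases.

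The first pattern is the larger fold change of the less abundant genes at a locus whose most abundant gene was called higher. Selection of the less abundant genes by their own call is argued against, since genes that were not called had the larger change at 88.9% of loci, 24 of 27. Selection by the filter for testing was not examined and stays open. Untested genes had a mean over both groups of at most 0.81 FPKM, so sparse genes could enter through their corticosterone value. At the chromosome 20 locus (7974577 to 8087005) the others had medians of 0.24 FPKM with vehicle and 1.56 with corticosterone. A filter at a mean of 1 FPKM uses both groups too and cannot decide. For noise of low values, the median difference of 0.477 exceeded all 10000 random sets, the highest being 0.15. Those sets drew loci whose most abundant gene was not called and so had little change for sparse genes to enlarge. They therefore cannot decide. A closer set was 76 loci whose most abundant gene was not called but rose at least as much as the smallest called rise. There the others rose more at 29 loci, with a median difference of -0.131. As these rises were not called themselves, noise of low values stays open. A candidate explanation is that the less abundant entries hold unspliced RNA of the same transcription unit, which could increase sooner than the spliced pool. The table has no exons or strand, and only 2 loci had a most abundant gene that was called lower, so this stays open. On chromosomes 17 (24242553 to 24295095) and 3 (29856790 to 30001316), a sparser gene was called lower, with log2 fold changes of -0.82 and -0.52. The most abundant genes there, not called, had -0.11 and -0.06. Those sparse genes were picked by their call, so they do not decide it. Against the pattern stand the 12 uncalled genes of the chromosome 1 locus at 24185451 to 24302581, and a pseudocount of 1 lowers the difference to 0.054.

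The second pattern is the excess of increases over decreases. Scaling that differs with abundance is argued against as the account of the calls, since the median log2 fold changes of the abundance bins differ by at most 0.0467, below the smallest called change of 0.29. A small tilt is present, as these medians rise from bin to bin, from -0.0185 below 1 FPKM to 0.0282 at 50 FPKM and above. A single scaling factor stays open: the median gene among those with a mean of at least 1 FPKM differs by 0.00939, but the scaling method is not given. One that centres on the median gene would set that value near 0 itself. Repeated counting of split loci is argued against as the whole account, since 75.7% of regions of a single direction were higher after joining loci within 100 kb. A response to corticosterone that is mostly an increase at 1 h stays open as a hypothesis, and differences in power between the directions were not tested.

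The third pattern is that called loci lie close together. Chance placement is argued against: 37 of the 126 called loci had another within 100 kb, against a median of 4 and a highest value of 18 in 1000 matched random sets. A candidate explanation is that the assembly split 1 transcription unit into several loci, for which the median of 0.243 speaks, seen in uncalled loci within 10 kb. It also required no excess at 100 kb to 1 Mb, where the median of 0.015 lay above the central 95% of random sets but below the highest of them, 0.018, while the share of loci in the same direction, 54.5%, lay below the upper end of its own central 95%, 54.6%. With the median and the share divided, splitting and a shared response of separate neighbouring genes cannot be told apart from these tables, which carry no gene models.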
